A study of Arabidopsis thaliana with 36 samples.

How the data were processed

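Seedlings of 4 genotypes (WT, atg2, atg5 and atg9) were sampled after 5 days in darkness, 0, 12 and 24 h after transfer to light, with 3 libraries per group, 36 in all. Per the labels' protocols, RNA was extracted with CTAB and lithium chloride and made into stranded total RNA libraries after depletion of ribosomal RNA. The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.4 and kallisto (version not stated). The transcriptome and its build are not given in the sources used here. Per the submitters' processing notes, kallisto assigned trimmed reads to transcripts and scaled TPM by effective transcript length. The deposited files hold its estimated counts per transcript, fractional where reads fit several transcripts, and the TPM. For 35 libraries a second deposited file held the same estimates, checked to agree within a relative difference of 0.0001 for 100% of transcripts.

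Estimated counts of 82190 transcripts were summed to 34212 genes and rounded. Gene names came from the reference annotation of the assembly TAIR10.1 (Arabidopsis thaliana, Columbia), in which 33437 of the 34212 gene identifiers were found. The genes include 133 of the plastid, 143 of the mitochondrion and 15 for ribosomal RNA. Library totals ranged from 1.22 to 14.79 M counts and the WT libraries of the light groups were the shallowest, so small changes in genes with few counts were not resolved there. CPM values are counts divided by the library size after TMM scaling.

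Counts were modelled in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, TMM scaling, filterByExpr by group and quasi-likelihood tests. This left 19054 genes, 24 residual degrees of freedom, a common dispersion of 0.03864 and a median prior of 10.17 degrees of freedom. Adjusted p-values (Benjamini-Hochberg, threshold 0.05) were taken over all tested genes and, where so stated, over a list alone. The comparisons were light against dark in each genotype, each mutant and the mean of the 3 mutants against WT at each time, the light response of the mutants' mean minus that of WT, and atg9 against the mean of atg2 and atg5. These comparisons, the gene lists and most of the alternatives were fixed before the data were examined.

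Gene lists (25, written from general knowledge, 399 identifiers of which 397 were in the files) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with an estimated correlation. They cover autophagy, the light-harvesting antenna, photosystem subunits, chlorophyll biosynthesis, the Calvin cycle, plastid-encoded and mitochondrion-encoded genes, plastid transcription, plastid protein import, carotenoid and thylakoid lipid synthesis, light signalling, the clock, carbon starvation, amino acid catabolism, lipid mobilisation, photorespiration, seed storage, root markers, salicylic acid defence, jasmonate response, flavonoid synthesis, oxidative stress, the unfolded protein response, the proteasome and senescence. No cells were typed; seed storage genes and root markers served as markers of ungerminated seed and of the share of root in whole seedlings.

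Genes were named by a rule. ATG2, ATG5 and ATG9 were given in every library. For WT light responses, the mean of the mutants against WT and the difference in light response, the 5 largest rises and 5 largest falls with an adjusted p under 0.05 and a mean of at least 1 CPM over the groups compared were named, for mutant comparisons only where the fitted change had the same sign in all 3 mutants. For single mutants against WT, 3 in each direction were named. For lists, up to 4 members with the smallest adjusted p and any member of the opposite direction were eligible. Folds against a group with 0 counts are lower bounds with a floor of 3 counts over the group, and groups with 1 to 3 counts are given as a ratio with a 95% interval. Intervals cover counting error only, since reads are not independent molecules. Bounds cover it only in the group at 0, with the other at its observed CPM, so true folds may lie lower. Where all 3 mutant groups had 0 counts, CPM is given in place of a bound. Genes shown in the plots of marker transcripts were chosen after the values were seen.

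The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For atg9 against WT at 0 h, edgeR recovered 41% of the 2-fold and 99% of the 4-fold genes with 8 false calls of 18296. At 12 h it recovered 34% and 94%, with 6 false calls of 18363. In both, camera called the changed list and 0 of 10 unchanged lists. This does not show that list calls hold in the real data, where most were lost with an estimated correlation.

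Fixed beforehand were runs with DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, replicate number as a block, a fit to the compared groups alone, counts rebuilt from length-scaled TPM, organelle genes left out, an estimated correlation between genes and each library left out in turn. Added after the data were seen were runs without 5 libraries that stood apart, without the 15 rRNA genes, with library class as a term (10 libraries with a narrow and 26 with a wide spread of length minus effective length over transcripts of at least 2000 bases, parted at 115), with atg2 and atg9 alone at 12 h (the 3 libraries labelled atg5 12 h left out, with and without the 5) and with counts thinned to the shallowest library at each time. The size factors used in edgeR were medians of ratios over genes counted in every library, and the Wald test used the positive-count variant over all genes. Random splits of the libraries were drawn 30 times where more than 10 exist.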

Results

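Arabidopsis seedlings of the wild type (WT) and of atg2, atg5 and atg9, mutants named for genes of autophagy (the pathway that delivers cell contents to the vacuole), were grown for 5 days in darkness on liquid medium with sucrose and then moved to light. Total RNA was sequenced at 0 h (dark), 12 h and 24 h of light, in 3 libraries for each of 12 groups, 36 in all. The question named by the series is how autophagy mutants green when carbon is limiting. Depth differed between groups (mean ± SD, n = 3). Dark WT held 3.65 ± 0.662 M counts, WT at 12 h 1.47 ± 0.331 M and WT at 24 h 2.19 ± 0.490 M. Ribosomal RNA took 5.27% to 84.8% of the counts in 35 libraries and 99.89% in atg2 24 h replicate 2, which was left with 5948 counts outside rRNA and 34 genes with at least 10 counts. Values after CPM (counts scaled to library size) are means ± SD, log2 changes are ± SE, and each group has n = 3. The labels call the 3 libraries biological triplicates without giving each its own vessel, so the p-values measure the spread between these samples, which may in part be technical.

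The targeted genes came first. ATG2, which codes for a lipid transfer protein of the growing autophagosome, stood at 12.9 to 20.7 CPM in 8 of the 9 atg2 libraries and at 0 in atg2 24 h replicate 2, against 44.5 to 61.0 in WT, 61.7 to 84.7 in atg5 and 50.1 to 66.7 in atg9. ATG9, which codes for the membrane protein of autophagosome seed vesicles, was 1.01 to 3.38 CPM in all 9 atg9 libraries, 29.3 to 40.7 in the atg2 libraries other than replicate 2 at 24 h, and 25.7 to 41.7 in atg5. ATG5, whose product helps attach ATG8 to membranes, was higher, not lower, in the atg5 libraries, with 12.7 to 20.7 CPM against 1.67 to 7.23 in WT, 3.64 to 7.39 in atg9 and 5.79 to 10.2 in atg2 without replicate 2 at 24 h. In WT, ATG9 was 23.4, 24.2 and 24.3 CPM in the dark, but 1.67, 19.3 and 2.33 in the libraries labelled WT 12 h replicates 1, 2 and 3, and 4.13, 16.6 and 14.7 in those labelled WT 24 h replicates 1, 2 and 3. At the dark WT level, the libraries labelled WT 12 h replicates 1 and 3 and WT 24 h replicate 1 would have held 28.7, 61.8 and 46.4 ATG9 counts. They held 2, 6 and 8. WT 24 h replicates 2 and 3 also lay under that level, with 56 and 55 counts where 80.7 and 89.6 were expected. Leaving out the 5 libraries that stood apart, ATG9 fell in WT at 24 h by -0.63 (log2, edgeR adjusted p = 0.0183).

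**Figure D1:**
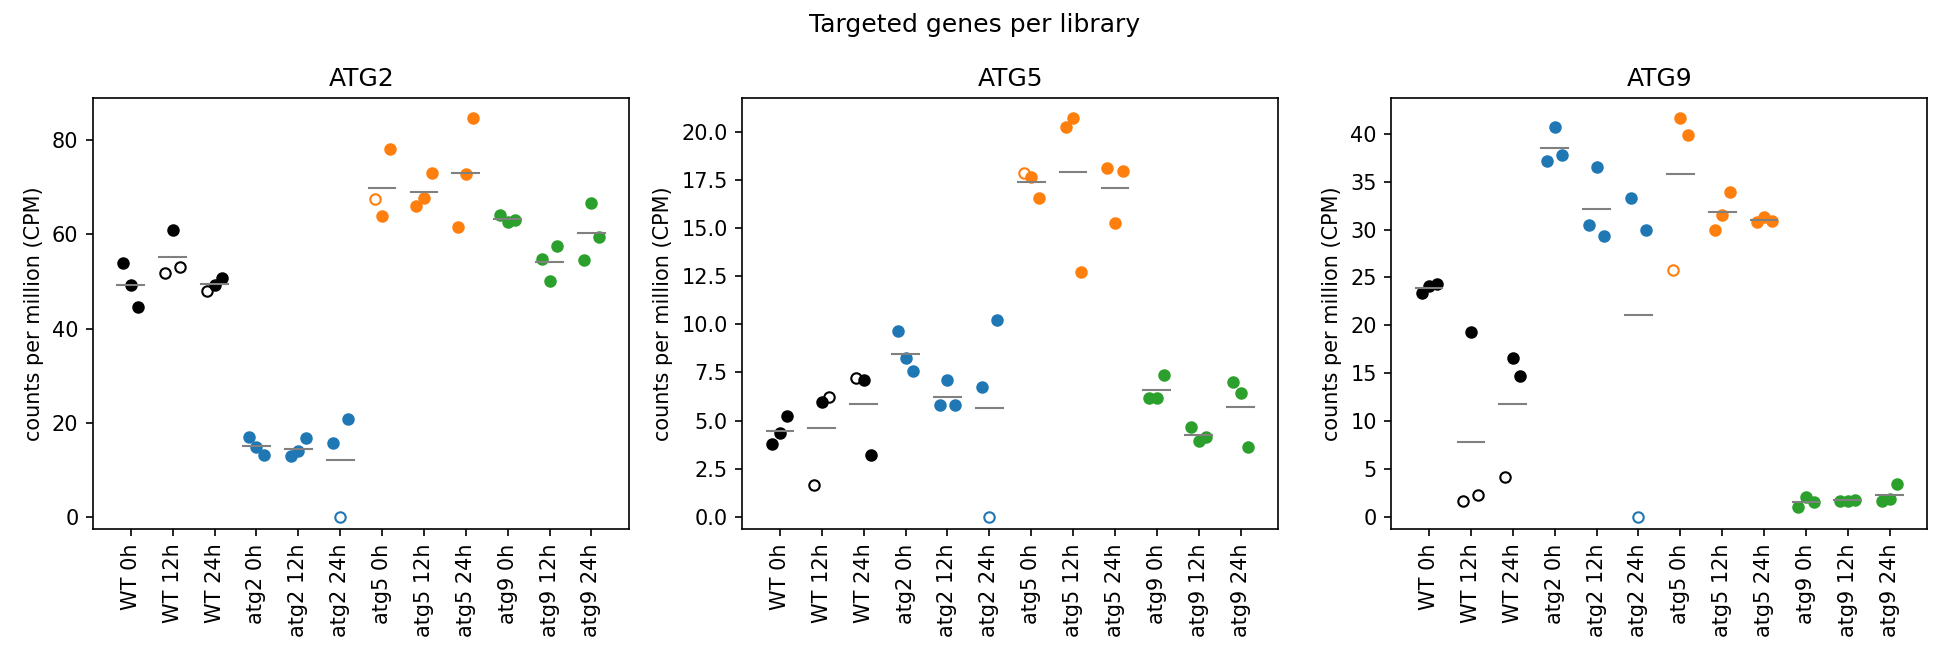
CPM of ATG2, ATG5 and ATG9 in each library, by genotype and hours of light. Filled and open points are libraries, open for the 5 left out together in further runs, and grey lines are group means. ATG9 lay at 1.67, 2.33 and 4.13 CPM in 3 libraries labelled WT in the light, near the 1.01 to 3.38 CPM of the atg9 libraries.

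Transcripts with a strong time course also set libraries apart. CCA1, a morning-phased clock gene, was 0.775 to 2.97 CPM in the 3 libraries labelled WT 12 h, 1.53 to 1.74 in atg2 12 h and 0.886 to 1.87 in atg9 12 h, but 91.0, 109 and 110 CPM in the 3 libraries labelled atg5 12 h. Every library at 0 h or 24 h other than the failed atg2 24 h replicate 2 had CCA1 at 60.9 CPM or more. LHCB1.2, an antenna protein gene with near-identical copies, was 34.2 to 123 CPM in the dark libraries except atg5 0 h replicate 1, which had 683. CRA1, which codes for a seed storage cruciferin, was 14.5, 11.9 and 10.2 CPM in dark WT and 1020, 796 and 815 in dark atg9. In the libraries labelled WT 12 h replicates 1 to 3 it was 134, 23.8 and 130, and in those labelled WT 24 h replicates 1 to 3 it was 40.3, 1.19 and 2.41. AT3G32990, a transcribed pseudogene, was 58.2 to 153 CPM in the WT libraries and at most 27.1 in any mutant library. CCA1, LHCB1.2 and CRA1 were chosen for the plot of marker transcripts, and AT3G32990 for this comparison, after their values were seen. Each comparison was also run without 5 libraries that stood apart in transcripts named above or in rRNA. These were the libraries labelled WT 12 h replicates 1 and 3 and WT 24 h replicate 1, with low ATG9. The others were atg5 0 h replicate 1, with high LHCB1.2, and atg2 24 h replicate 2, almost all rRNA. That leaves WT 12 h with 1 library, replicate 2, assumed to vary like the other groups. This was the shallowest WT library, with 75.96% rRNA, 292459 counts outside rRNA and 5964 genes with at least 10 counts. All results for WT at 12 h without the 5 libraries rest on it.

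**Figure D2:**
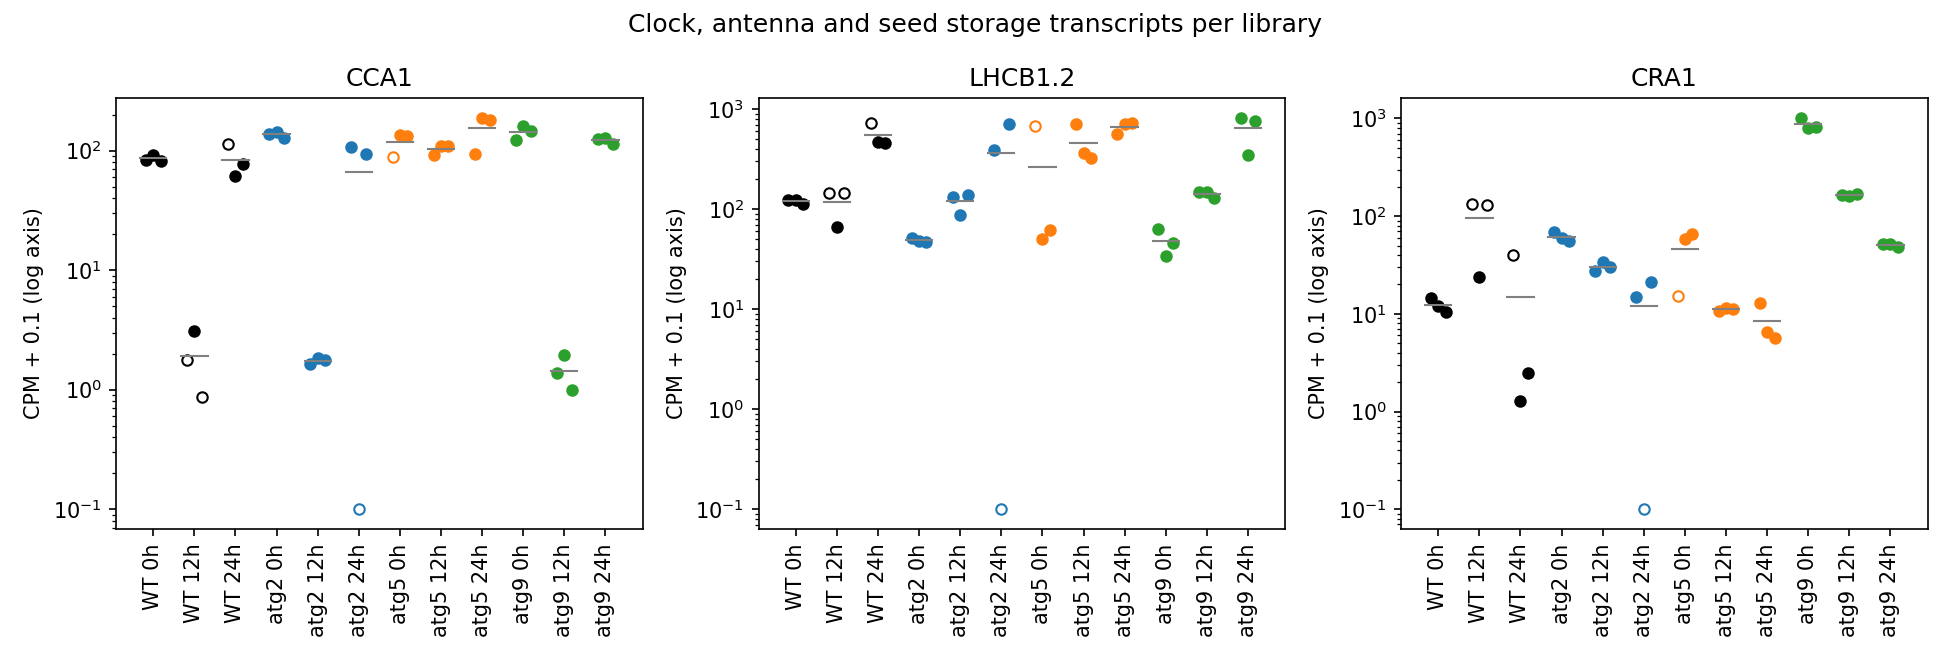
CPM of CCA1, LHCB1.2 and CRA1 on a log axis in each library, by genotype and hours of light, with filled points for libraries, open points for the 5 that stood apart and grey lines for group means. CCA1 was 91.0 to 110 CPM in the libraries labelled atg5 12 h and at most 2.97 CPM in those labelled 12 h of the other genotypes.

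LHY and CCA1, the paired morning clock genes, fell in WT after 12 h of light by log2 changes of -5.75 ± 0.42 and -5.95 ± 0.46 (edgeR adjusted p = 1.5e-11 and 3.95e-11), with RVE8 (-2.75 ± 0.34) and PRR9 (-4.38 ± 0.69), while TOC1, which represses the morning genes, rose by 1.01 ± 0.19. ELIP1 and ELIP2, early light-induced proteins, fell by -4.42 ± 0.51 and -4.29 ± 0.44, and PIF4 and PIF5, transcription factors degraded in light, by -2.38 ± 0.33 and -2.19 ± 0.26. PORA, the protochlorophyllide reductase of etiolated tissue, fell from 66.8 ± 4.22 to 6.27 ± 3.54 CPM (2.97 in WT 12 h replicate 2). Antenna genes LHCB2.1, LHCB2.2 and LHCB1.1, whose copies are too alike for their reads to be divided with certainty, fell by -2.95 ± 0.51, -3.55 ± 0.64 and -2.92 ± 0.58. Rubisco small subunit RBCS1B, also one of several near-identical copies, rose by 2.26 ± 0.41, and photorespiratory SHM1 and AGT1 by 2.12 ± 0.40 and 1.68 ± 0.30. All of these kept their direction and their call when any 1 library, or all 5 that stood apart, were left out.

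By list at 12 h in WT (limma camera), light signalling had 9 of 22 members lower and 0 higher (median log2 change -0.44, adjusted p = 1.12e-06), and the clock 6 lower and 3 higher of 10 (adjusted p = 0.00103). The antenna had 6 lower and 1 higher of 21 (median -0.02, mean -0.54, adjusted p = 0.00237). Photosystem subunits had 4 of 27 higher, 5 adjusted over the list alone (adjusted p = 0.000415 for the list), with PSAN at 1.58 ± 0.40. Higher members numbered, for the Calvin cycle, 5 of 21, 10 adjusted over the list alone (adjusted p = 8.8e-05), photorespiration 3 of 13 (adjusted p = 0.000249), plastid transcription 2 higher and 1 lower of 20 (adjusted p = 0.027), and plastid-encoded genes 4 higher and 1 lower of 60 (adjusted p = 0.0063). With an estimated correlation, each of these lists had an adjusted p = 0.999. Seed storage and oil body proteins had 12 of 14 higher (median 3.19, adjusted p = 6.75e-18, and adjusted p = 0.0482 with an estimated correlation). OLEO1 of the oil body coat rose by 4.75 ± 0.66. This rise came from the libraries labelled WT 12 h replicates 1 and 3. With those 5 libraries left out, the seed storage calls were not kept and the median was 0.86. The Calvin cycle, photorespiration and plastid transcription then lost their camera calls, and the antenna median was -1.34.

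Among the largest changes at 12 h in WT, SQE6, a squalene epoxidase gene, was at least 17.5-fold higher, where the bound takes 3 counts over a group without any. AT1G72910, AT1G61300, AT3G46250 and AT4G09300 were at least 32.9-fold, 15.4-fold, 9.26-fold and 8.23-fold higher, and AT3G26430, AT3G53400, AT3G55580 and AGL44, a MADS-box gene, at least 13.3-fold, 9.72-fold, 5.83-fold and 3.02-fold lower. Leaving out all 5 libraries, edgeR no longer called AT1G72910, AT1G61300, AT3G26430, AT3G53400, AT3G55580 and AGL44. AT3G46250 and AT4G09300 lost their calls without WT 12 h replicate 2 (adjusted p = 0.119 and 0.0994), where their bounds were 4.85-fold and 3.64-fold, and that of AT3G26430 was 4.51-fold without WT 0 h replicate 3. AT3G46250 was also not called without WT 0 h replicates 1, 2 or 3 or the library labelled WT 12 h replicate 1 (0.0738, 0.0709, 0.062 and 0.0968), nor AT1G61300 and AT3G55580 without that labelled WT 12 h replicate 3 (0.0603 and 0.0566). AT3G26430 and AGL44 each needed the libraries labelled WT 12 h replicates 1, 2 and 3 (0.105, 0.0573 and 0.204, and 0.103, 0.0554 and 0.212) and WT 0 h replicate 3 (0.184 and 0.0828), and AGL44 also WT 0 h replicates 1 and 2 (0.0523 and 0.0501). In total edgeR called 1546 genes, 776 higher and 770 lower. It called 1042 without the 5 libraries, of which 373 were shared. Thinning the libraries at each time to the shallowest gave 813. The count was 962 and 1007 without WT 0 h replicates 1 and 2, and 882 and 753 without the libraries labelled WT 12 h replicates 1 and 3. The share called higher was 50.2%, but 65.4% with DESeq2 size factors, which moved the median of all genes to 0.13 (log2), and 37.2% with the DESeq2 Wald test.

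By 24 h in WT, 25 of 27 nuclear photosystem subunits were higher, 26 adjusted over the list alone, with a median log2 change of 1.69 (camera adjusted p = 1.81e-17): PSAN 2.62 ± 0.39, PSAH2 2.02 ± 0.36, PSAG 1.82 ± 0.35 and PSBP1 2.23 ± 0.43. The antenna had 12 of 21 higher, 18 adjusted over the list alone (median 1.41, adjusted p = 1.66e-12), with LHCA3 at 1.98 ± 0.43 and LHCB3 at 1.74 ± 0.38. The Calvin cycle had 12 of 21 higher (adjusted p = 1.4e-06) and photorespiration 8 of 13 (adjusted p = 2.24e-06), with RBCS1B at 2.42 ± 0.39 and SHM1 at 2.15 ± 0.40. Plastid-encoded genes had 6 of 60 higher (median 0.39, adjusted p = 4.41e-06), ATCG00470 by 1.82 ± 0.25. PORA and PORB fell by -3.09 ± 0.33 and -1.67 ± 0.23. With an estimated correlation the adjusted p was 0.668 for the photosystem, antenna and photorespiration lists and 0.961 for the Calvin cycle and plastid-encoded genes.

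Lipid mobilisation at 24 h in WT had 10 of 18 lower and 1 higher (median -0.54, camera adjusted p = 0.00325, and adjusted p = 0.961 with an estimated correlation). MLS and ICL, the glyoxylate cycle enzymes that turn stored fat into sugar, fell by -1.69 ± 0.32 and -2.16 ± 0.41, ICL from 3120 ± 164 to 698 CPM, and PCK1 of gluconeogenesis by -1.37 ± 0.27, while PMDH2 rose by 1.403 ± 0.33. Carbon starvation markers had 5 of 14 higher, 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.00365): TPS11 1.35 ± 0.20, DIN1 1.301 ± 0.21 and BZIP1 2.21 ± 0.45. The clock had 4 of 10 lower (adjusted p = 0.0167), with GI at -1.64 ± 0.28 and LUX at -1.21 ± 0.23, and ATG8e, which codes for an autophagosome-bound ubiquitin-like protein, rose by 1.67 ± 0.28. Seed storage had 1 of 14 higher (median 1.45, adjusted p = 0.0165), which rested on the library labelled WT 24 h replicate 1: without it, or without all 5 libraries, the median was -0.13. For the carbon starvation, clock and seed storage lists the adjusted p was 0.961 with an estimated correlation. Light signalling had 5 higher and 5 lower of 22 (adjusted p = 0.0573) and chlorophyll biosynthesis 5 higher and 2 lower of 26 (adjusted p = 0.644).

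The largest rises at 24 h in WT were those of BEE3, a brassinosteroid response factor (0.369 ± 0.142 to 25.3 ± 4.39 CPM), NDA1, a mitochondrial NADH dehydrogenase (0.457 ± 0.429 to 14.6 ± 7.03 CPM), AT4G14060, at least 14.2-fold, and AT3G53250, whose ratio was 40.3 (95% counting interval 10.6 to 341). ATGA2OX1, which inactivates gibberellins, was at least 7.90-fold lower, and AAE12, an acyl-activating enzyme gene, fell with a ratio of 65.2 (11.4 to 2600). AT1G72910 was at least 14.2-fold higher, a call lost without the library labelled WT 24 h replicate 1 (edgeR adjusted p = 0.313, bound 1.29-fold). AT3G22970, AT4G22460 and AT3G51238 were at least 32.5-fold (20.1-fold without WT 0 h replicate 1), 9.66-fold and 7.90-fold lower. They lost their calls without WT 24 h replicate 3 (adjusted p = 0.119, 0.0663 and 0.117) or replicate 2 (0.107, 0.0566 and 0.101). The DESeq2 Wald test did not call AT3G22970 (0.601). AT3G22970 was also not called without WT 0 h replicates 1 or 3 or the library labelled WT 24 h replicate 1 (0.108, 0.0816 and 0.0654), nor AT3G51238 without WT 0 h replicates 2 or 3 or that library (0.106, 0.0805 and 0.0546). The count was 1976, 1128 higher and 848 lower, and 2782 without the 5 libraries, of which 1739 were shared. Leaving out WT 0 h replicates 1, 2 or 3 gave 1202, 1287 or 1278, and leaving out WT 24 h replicates 2 or 3 gave 1284 or 1134.

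In the mutants' light responses at 24 h the antenna had 19 of 21 members higher in atg2 (median log2 change 2.28), 13 in atg5 (1.401) and 19 in atg9 (2.51), with camera adjusted p = 9.65e-26, 4.5e-30 and 1.87e-40. Photosystem subunits had 26, 27 and 27 of 27 higher (medians 2.21, 1.64 and 2.33). With an estimated correlation the adjusted p for the antenna was 0.224, 0.0791 and 0.0191, and for the photosystems 0.372, 0.0791 and 0.046. At 12 h, 21 of 27 photosystem and 17 of 21 Calvin cycle genes were higher in atg2 and 23 and 17 in atg9 (camera adjusted p at most 5.73e-11, and adjusted p = 0.387, 0.365, 0.321 and 0.321 with an estimated correlation). In the libraries labelled atg5 12 h, 5 photosystem genes were higher, 23 adjusted over the list alone (adjusted p = 1.59e-25, and adjusted p = 0.395 with an estimated correlation). Seed storage transcripts fell in atg9, with 8 of 14 lower at 12 h and 10 at 24 h (medians -1.51 and -2.39, adjusted p = 7.28e-08 and 2.87e-20, and adjusted p = 0.321 and 0.0191 with an estimated correlation). Flavonoid genes had 7 higher and 1 lower of 17 in atg2 at 12 h (adjusted p = 1.13e-07) and 8 higher and 2 lower in atg9 (adjusted p = 2.27e-05), with adjusted p = 0.365 and 0.399 with an estimated correlation. Plastid-encoded genes had 12 of 60 higher at 12 h in atg2 (adjusted p = 0.00294) but 15 lower and 3 higher in atg9 (median -0.18, adjusted p = 0.000377), with adjusted p = 0.992 and 0.972 with an estimated correlation.

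In atg2, edgeR called 4172 genes at 12 h (2253 higher, 1919 lower) and 3005 at 24 h (1510 and 1495). In atg9 it called 3199 (1681 and 1518) and 2231 (1243 and 988), and in atg5 321 (104 and 217) and 2816 (1565 and 1251). The atg5 count at 12 h depended on single libraries and settings. It was 2004 without atg5 0 h replicate 1, 6 and 4 without replicates 2 and 3, 768, 38 and 48 without the libraries labelled atg5 12 h replicates 1, 2 and 3, and 582 without atg5 24 h replicate 1. Without the 5 libraries it was 2654, with no low-count filter 1024, with library class as a term 94 and with thinned libraries 47. A fit to the atg5 dark and 12 h groups alone called 0 genes in edgeR (2314 at an unadjusted p under 0.05; the DESeq2 Wald test on all groups called 289). At 24 h the atg5 count was 29 in a fit to its own groups, 4268 without the 5 libraries, 1452 with thinned libraries, 1432 and 1444 without atg5 0 h replicates 2 and 3, and 1177 and 1448 without atg5 24 h replicates 2 and 3. The atg2 count at 24 h was 1698 and 1821 without atg2 24 h replicates 1 and 3. In atg9 the 12 h count was 2065 and 2088 without atg9 12 h replicates 1 and 2. The 24 h count was 1346 and 1391 without atg9 24 h replicates 1 and 3. Thinned libraries gave 1404 in atg2 at 12 h and 984 and 1212 in atg9.

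In the dark, seed storage transcripts, the markers of ungerminated seed, were higher in the mutants than in WT, and many autophagy transcripts moderately so. The share of such seed was not measured. Seed storage members called higher in atg2, atg5 and atg9 numbered 10, 6 and 13 of 14 (medians 2.78, 1.90 and 4.78). For autophagy they numbered 13, 16 and 17 of 37 (medians 0.55, 0.54 and 0.59). On the mean of the mutants, 12 of 14 seed storage genes were higher, 13 adjusted over the list alone (median log2 change 3.14, camera adjusted p = 3.75e-34, and adjusted p = 0.0016 with an estimated correlation). PER1, a seed peroxiredoxin, was at 0.289 CPM in WT against 7.12, 5.67 and 43.8 in atg2, atg5 and atg9, and EM6, a late embryogenesis protein, at 1.26 against 23.6, 11.3 and 44.7. OLEO1 was at 0.738 against 8.17, 6.21 and 50.7 ± 3.21, and the 2S albumin SESA5 had a ratio of 205 (95% counting interval 70.1 to 994). Of 37 autophagy genes 20 were higher and 1 lower (median 0.50, adjusted p = 3.56e-05, and adjusted p = 0.991 with an estimated correlation), or 21 and 2 adjusted over the list alone. ATG8e rose by 2.27 ± 0.24 and ATG8a by 1.64 ± 0.18, from 6.31 ± 1.06 and 9.24 ± 1.56 CPM in WT, and the kinase complex genes ATG1a and ATG101 by 1.23 ± 0.15 and 1.82 ± 0.26. ATG9, low in atg9 itself, was the member that fell. Senescence and chlorophyll breakdown genes had 6 of 12 higher (median 1.27, adjusted p = 2.83e-06, and adjusted p = 0.184 with an estimated correlation). NYE1 and NYE2, which remove magnesium from chlorophyll, rose by 2.07 ± 0.26 and 2.27 ± 0.47. When the 5 libraries were left out, autophagy and senescence had adjusted p = 0.00164 and 0.00335 with an estimated correlation.

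Flavonoid genes had 4 of 17 lower in the dark mutants (median -0.58, camera adjusted p = 0.000159), with the entry enzyme CHS at -1.15 ± 0.19. Jasmonate genes had 5 of 10 lower, 6 adjusted over the list alone (median -0.60, adjusted p = 0.00901), with LOX2, the plastid lipoxygenase of jasmonate synthesis, at -4.20 ± 0.43, from 11.3 ± 1.43 CPM in WT to 0.232, 1.64 (0.643 without atg5 0 h replicate 1) and 0.425. Both lists had an adjusted p = 0.991 with an estimated correlation. The unfolded protein response had 5 of 11 lower (median -0.43, adjusted p = 0.165), among them the chaperones CRT1 (-0.77 ± 0.13) and CNX1 (-0.62 ± 0.11), and BIP2, near-identical to BIP1 (-0.76 ± 0.12). Lipid mobilisation had 7 lower and 1 higher of 18 (adjusted p = 0.13), with MLS at -1.27 ± 0.24. Carbon starvation had 6 of 14 higher (adjusted p = 0.0682), with DIN1 at 1.12 ± 0.18 and DIN2 at 3.35 ± 0.57. Amino acid catabolism had 5 of 15 higher (LKR of lysine breakdown 1.54 ± 0.22), salicylic acid defence 5 higher and 1 lower of 11 (EDS5, the salicylate exporter, -1.196 ± 0.17) and photorespiration 3 of 13 higher (GLYK 1.12 ± 0.14), each with a camera adjusted p = 0.0643.

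Chloroplast lists gave few calls in the dark. The antenna had 0 of 21 members called in edgeR and adjusted p = 0.621 in camera. Photosystem subunits had 3 of 27 lower and chlorophyll biosynthesis 4 of 26 lower (both adjusted p = 0.501), including GSA1 of early tetrapyrrole synthesis (-0.98 ± 0.15) and PORB (-0.65 ± 0.18). The Calvin cycle had 2 of 21 lower, with the regulator CP12-1 at -1.58 ± 0.29. Plastid-encoded genes had 7 higher and 2 lower of 60, mitochondrion-encoded genes 5 and 9 of 64, plastid transcription 1 and 0 of 20 (the sigma factor SIG5, 2.12 ± 0.33). Plastid protein import had 1 and 3 of 14 (TIC55 1.11 ± 0.25, TOC159 -0.55 ± 0.13), carotenoid and thylakoid lipid synthesis 4 and 1 of 15 (LYCB 0.79 ± 0.22, MGD1 -0.60 ± 0.17) and light signalling 5 and 3 of 22 (COP1 0.61 ± 0.15, GLK1 -1.08 ± 0.25). The clock had 3 higher and 1 lower of 10 (RVE8 0.73 ± 0.16), root markers 1 and 2 of 11 (PHO1 1.01 ± 0.21), oxidative stress 2 and 1 of 12 (AOX1A 1.34 ± 0.18, FER1 -0.64 ± 0.15) and the proteasome 5 and 3 of 15 (PAB1 0.76 ± 0.20, RPN10 -0.88 ± 0.16). The antenna had 1 higher and 10 lower without the 5 libraries (median -0.49, adjusted p = 0.00499, and adjusted p = 0.583 with an estimated correlation).

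The largest rises in the dark mutants were those of genes at 0 in WT: AT5G59732, a long noncoding RNA, at least 47.8-fold, the seed metallothionein AtMT4b at least 31.1-fold, the gibberellin-regulated GASA2 at least 23.8-fold, the senescence protease SAG12 at least 20.7-fold and AT5G01732 at least 11.3-fold. SAG12 had 3, 1 and 1 counts in dark atg9, so its rise lay in atg2 and atg5. AT3G22970 was at 10.9 CPM in WT (88, 0 and 60 counts) and 0 in all 3 mutants. AT1G55335 was at 10.9 CPM in WT (124, 32 and 0 counts) and 1.41, 0 and 0 in atg2, atg5 and atg9. AT2G08986, AT2G07981 and AT1G40104 fell by -5.46 ± 1.25, -5.34 ± 1.25 and -4.64 ± 1.26. The DESeq2 Wald test did not call AT3G22970 or AT1G55335 (adjusted p = 0.312 and 0.448), nor did edgeR with library class as a term (both adjusted p = 1), and SAG12 was not called without WT 0 h replicate 1 (edgeR adjusted p = 0.0507). The mean of the mutants differed from WT in 4431 genes, 2231 higher and 2200 lower, and in 2776 and 2883 without WT 0 h replicates 1 and 2. The count was 5649 without the 5 libraries, of which 4320 were shared.

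Single mutants in the dark differed from WT in 2500 genes for atg2 (1376 higher, 1124 lower), 4177 for atg5 (2302 and 1875) and 4507 for atg9 (2384 and 2123). In atg2, SAG12, GASA2 and AtMT4b were at least 25.9-fold, 14.6-fold and 12.5-fold higher, and MAM1, of methionine-derived glucosinolate synthesis, AT3G22970 and AT5G39150 at least 15.8-fold, 68.6-fold and 15.3-fold lower. In atg5, the mitochondrial ATMG00210, AT5G59732 and SAG12 were at least 194-fold, 83.7-fold and 35.2-fold higher, AT5G64343 at least 166-fold lower, and AT3G63052 and AT7SL-1, the RNA of the signal recognition particle, fell by -9.69 ± 2.45 and -10.78 ± 2.70. ATMG00210 and these last 2 follow library class (narrow or wide) within other groups. ATMG00210 had 262 counts in the wide and 0 in the narrow dark atg9 libraries, but 0 in dark WT, all wide. AT7SL-1 had 5, 7 and 11 in the dark atg5 libraries, all wide. It had 5 in the wide and 5653 and 8085 in the narrow dark atg9 libraries. AT3G63052 had 2, 1 and 1 counts in dark atg5 and 4, 878 and 1632 in dark atg9. In atg9, the seed oil body dehydrogenase HSD1, AtMT4b and GASA2 were at least 182-fold, 74.9-fold and 53.9-fold higher, and AT1G55335, AT3G22970 and AT2G44130 at least 82.4-fold, 78.1-fold and 61.2-fold lower. HSD1 had 0, 416 and 448 counts in dark atg9, the 0 in the wide library. It was not called with library class as a term (edgeR adjusted p = 1), nor was AT1G55335 in atg9 (0.0689) or AT3G22970 in atg2 (1). Without WT 0 h replicate 1 the bounds of AT3G22970 were 42.5-fold in atg2 and 48.4-fold in atg9, and that of AT1G55335 in atg9 25.8-fold. The DESeq2 Wald test did not call HSD1 in atg9 (adjusted p = 0.343), AT3G22970 in atg2 or atg9 (0.523 and 0.429) or AT1G55335 in atg9 (0.428). AT1G55335 was also lost in atg9 without WT 0 h replicate 1 (0.0649), and AT3G22970 and AT5G39150 in atg2 without atg2 0 h replicate 2 (0.0616 and 0.0654). The atg2 count was 1634 and 1404 without atg2 0 h replicates 1 and 2, 1493 and 1616 without WT 0 h replicates 1 and 2, and 5276 in a fit to its own groups.

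Of 21 antenna genes 7 were higher on the mean of the mutants at 12 h, 14 adjusted over the list alone (median log2 change 1.04, camera adjusted p = 5.96e-10, and adjusted p = 0.984 with an estimated correlation), the 1 list of 25 that camera called (9 without atg2 24 h replicate 2 and 3 without WT 12 h replicate 2). Singly, 0, 14 and 1 were higher in atg2, atg5 and atg9 (medians 0.43, 1.95 and 0.77, adjusted p = 0.032, 4.02e-21 and 0.000141, and adjusted p = 0.998, 0.417 and 0.988 with an estimated correlation). On the mean of atg2 and atg9 alone, 2 were higher (median 0.60, adjusted p = 0.00122, and adjusted p = 0.969 with an estimated correlation). LHCB3, an inner trimer protein of photosystem II, was at 63.1 ± 26.5 CPM in the libraries labelled WT 12 h (32.7 in replicate 2) against 138 in atg2, 890 ± 98.8 in those labelled atg5 12 h and 187 in atg9, a log2 change of 2.12 ± 0.37, and LHCB5 rose by 1.64 ± 0.41. The antenna median was 2.06 without the 5 libraries, and 1.715 without these and the libraries labelled atg5 12 h. Photosystem subunits had 7 of 27 higher (PSAH2 2.28 ± 0.40, adjusted p = 0.107 for the list). The chlorophyll genes CRD1 and CAO rose by 1.24 ± 0.24 and 1.27 ± 0.29 (CAO was not called for atg2 and atg9 alone, edgeR adjusted p = 0.397), and CP12-1 fell by -2.14 ± 0.29. Plastid-encoded genes had 6 higher and 11 lower of 60 (ATCG00330 1.82, ATCG01130 -2.55), autophagy 7 higher and 3 lower of 37 (adjusted p = 0.211) and seed storage 5 of 14 lower (median -1.13, adjusted p = 0.125). The seed storage direction came from the libraries labelled WT 12 h replicates 1 and 3; without the 5 libraries 0 of 14 passed and the median was 1.03.

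AT2G08986 and AT1G40104 were the most reduced at 12 h that lost no call in any setting, at 163 and 81.4 CPM in the libraries labelled WT 12 h against 0, 5.74 and 0.464 and 0, 3.90 and 0.152 in atg2, atg5 and atg9. The WT means rest on replicate 2: AT2G08986 had 36, 307 and 4 counts and AT1G40104 25, 149 and 5 in the libraries labelled WT 12 h replicates 1 to 3. AT5G31770, a pseudogene, was at 36.7 against 0, 0.864 and 0.169 (not called without WT 12 h replicate 2, edgeR adjusted p = 0.0813), and AT3G22970 and AT2G04380 were at 6.06 and 4.46 CPM (20, 1 and 0, and 11, 1 and 7 counts) against 0 in all 3 mutants. AMSH2, a deubiquitinase gene, AT3G26430, AT3G53400, AT1G27580 and AT3G47295 were at least 5.54-fold, 13.7-fold, 9.95-fold, 7.29-fold and 4.02-fold higher. Without the 5 libraries the calls of these 5 genes, AT3G22970 and AT2G04380 were not kept. Leaving out the library labelled WT 12 h replicate 1 ended the calls of AT3G22970, AT3G26430, AT3G47295 and AT1G27580 (0.497, 0.0722, 0.0583 and 0.118). Leaving out that labelled replicate 3 ended those of AT3G26430, AT3G47295 and AT1G27580 (0.163, 0.156 and 0.234), and AT1G27580 also needed WT 12 h replicate 2 and atg5 12 h replicate 1 (0.066 and 0.061). The count was 2446 (1119 higher, 1327 lower), and 1230 and 1226 without the libraries labelled WT 12 h replicates 1 and 3. With thinned libraries it was 741. The share called higher was 45.8%, but 31.1% with DESeq2 size factors and 67.1% with the DESeq2 Wald test, where the median of all genes was 0.13 (log2).

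Single mutants at 12 h differed from the libraries labelled WT 12 h in 2301 genes for atg2 (1104 higher, 1197 lower), 3028 for atg5 (1587 and 1441) and 1672 for atg9 (790 and 882). AT2G08986 and AT1G40104 were at least 728-fold and 376-fold lower in atg2. ATMG00285, of the mitochondrial respiratory chain, and AT3G22555 were at least 1074-fold and 185-fold lower in atg9, with AT1G40104 at -8.88 ± 1.63. All atg9 12 h libraries are wide, and ATMG00285 varied with class in atg9 24 h. Without WT 12 h replicate 2 the bounds were 98.9-fold for AT2G08986 and 74.1-fold for AT1G40104 in atg2 and 30.6-fold for AT3G22555 in atg9, which had 6, 49 and 2 counts in the libraries labelled WT 12 h. VIM4, a DNA methylation factor, was at least 15.7-fold lower in atg5. AT5G31702 was at least 164-fold lower in atg2, a call lost without WT 12 h replicate 2 (edgeR adjusted p = 0.137, bound 17.3-fold). In atg5, AT3G22970 and AT2G04380 were at least 27.4-fold and 24.8-fold lower (1.79-fold and 14.3-fold without the library labelled WT 12 h replicate 1) and SDH3-2, QQS, a regulator of starch content, and AT3G26430 at least 30.6-fold, 10.04-fold and 10.6-fold higher. In atg2, AT3G26430, AT3G53400 and AT5G38910 were at least 13.7-fold, 11.2-fold and 6.14-fold higher, and in atg9, AT3G26430, AT1G27580 and AT2G37480 at least 16.8-fold, 11.4-fold and 10.6-fold. These 11 calls in atg5, atg2 and atg9 were not kept without the 5 libraries. AT3G26430 also lost its call without the libraries labelled WT 12 h replicates 1 or 3 in atg2 (0.0822 and 0.171), atg5 (0.0938 and 0.198) and atg9 (0.0656 and 0.134), as did AT1G27580 in atg9 (0.0642 and 0.131) and SDH3-2 in atg5 (0.0827 and 0.161). With library class as a term AT3G22970, AT2G04380 and SDH3-2 were not called in atg5 (0.118, 0.0504 and 0.0522). The most extreme loss was that of AT3G22970 in atg5 without that labelled WT 12 h replicate 1 (0.603), and AT2G37480 in atg9 was lost without several libraries, most without that labelled WT 12 h replicate 3 (0.211). Without the libraries labelled WT 12 h replicates 1 or 3 the counts were 1297 or 1200 for atg2, 1894 or 1625 for atg5 and 965 or 1102 for atg9, and 1080, 1090 or 1070 for atg9 without atg9 12 h replicates 1, 2 or 3. With thinned libraries they were 430, 811 and 410. A fit to its own groups gave 1706 for atg5. The shares called higher, 48.0%, 52.4% and 47.3% for atg2, atg5 and atg9, were 36.6%, 33.8% and 38.0% with DESeq2 size factors and 65.4%, 65.4% and 66.0% with the Wald test.

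At 24 h, 13 of 37 autophagy genes were higher in the mutants and 1 lower, 15 and 1 adjusted over the list alone (median log2 change 0.43, camera adjusted p = 0.0135, and adjusted p = 0.984 with an estimated correlation). ATG1a rose by 1.14 ± 0.16, ATG18h by 0.81 ± 0.16 and ATG8a by 0.90 ± 0.19. The antenna had 4 of 21 higher, 7 adjusted over the list alone (median 0.79, adjusted p = 1.11e-05, and adjusted p = 0.984 with an estimated correlation), and 17 without the 5 libraries (median 1.18). LHCB4.3 of the minor antenna rose by 1.66 ± 0.40, a call lost without WT 24 h replicate 2 (edgeR adjusted p = 0.0877). Photosystem subunits had 8 of 27 higher (adjusted p = 0.0411), with PSAH1 at 1.12 ± 0.27, photorespiration 7 of 13 (adjusted p = 0.000288) and salicylic acid defence 5 higher and 1 lower of 11 (adjusted p = 0.00226). In that list PBS3 of salicylate synthesis rose by 2.82 ± 0.47 and PAD4 by 1.39 ± 0.22, and EDS5 fell by -0.94 ± 0.19. Mitochondrion-encoded genes had 5 higher and 5 lower of 64 (median 0.16, adjusted p = 0.0411). Seed storage had 0 of 14 called by edgeR but a median of 0.73 (camera adjusted p = 7.69e-05), and 8 higher without the 5 libraries (median 2.28). The photosystem, photorespiration, salicylic acid, mitochondrial and seed storage lists each had an adjusted p = 0.984 with an estimated correlation. Of single genes, HLS1, an apical hook regulator, fell by -1.95 ± 0.27, the chaperones CNX1 and CRT1 by -0.74 ± 0.12 and -0.85 ± 0.13, and LYCB of carotene synthesis rose by 1.301 ± 0.24.

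**Figure D3:**
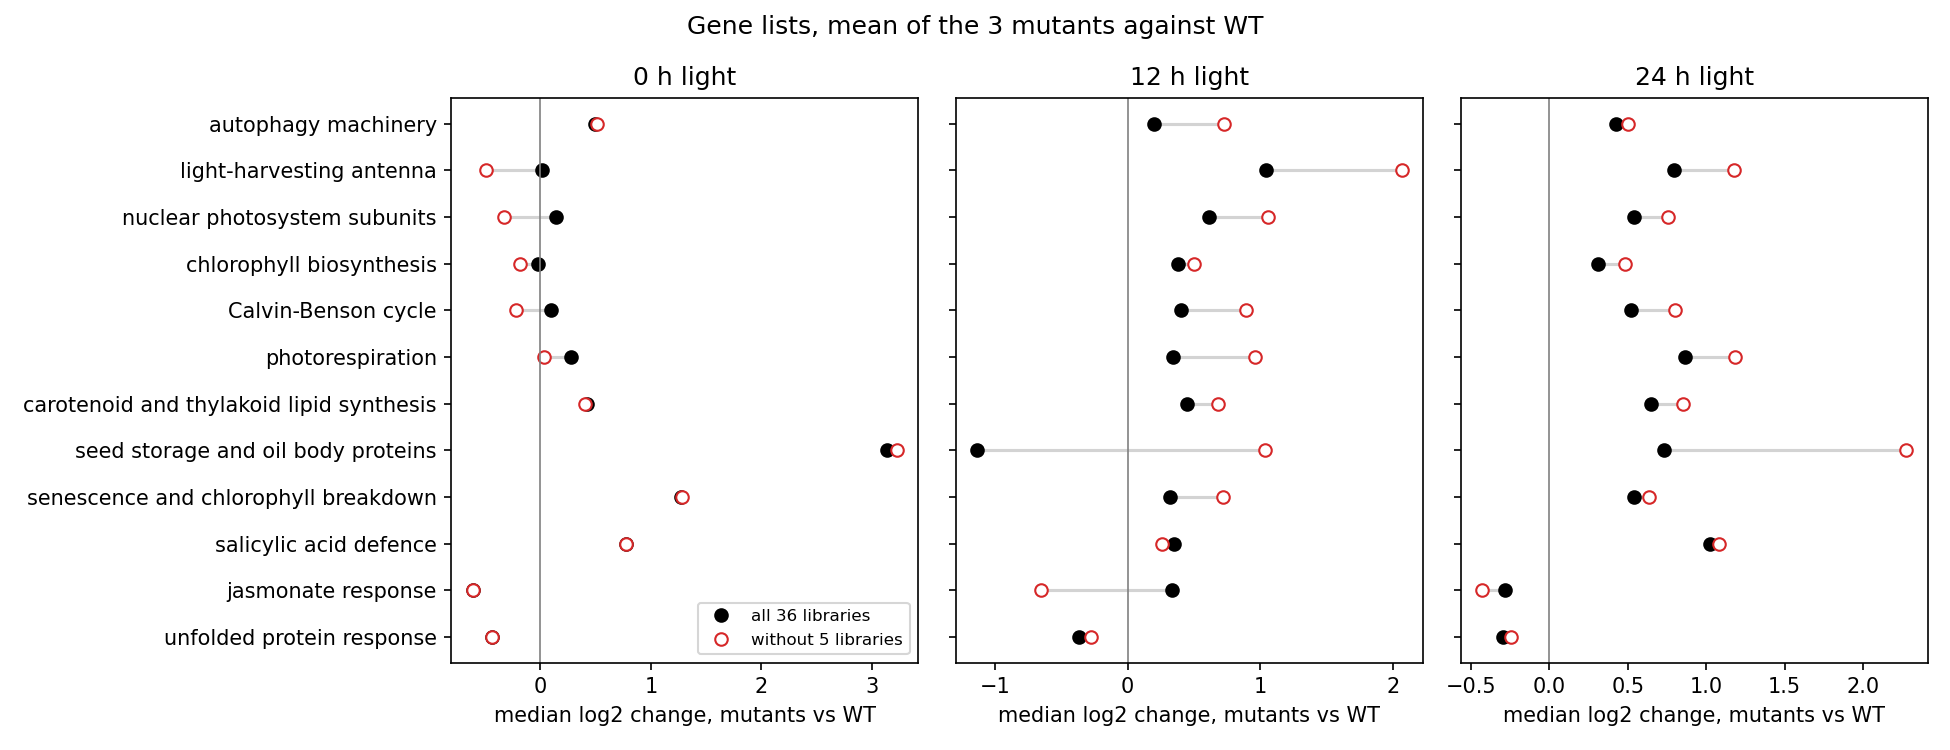
Median log2 change of 12 gene lists for the mean of the 3 mutants against WT at 0, 12 and 24 h of light; black points use all 36 libraries and open red points leave out the 5 that stood apart. The seed storage median was 3.14 at 0 h with all libraries and 3.22 without the 5, but -1.13 and 1.03 at 12 h.

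The largest changes at 24 h included AT1G03106, at least 9.64-fold higher, AT1G16635, a noncoding RNA at 8.45 CPM in WT (4.68 without the library labelled WT 24 h replicate 1) against 0.224, 0 and 0.828, and AT3G32990, which fell by -4.64 ± 0.84. AT4G06477, a pseudogene, rose by 6.94 ± 1.66, with 4245 CPM in atg2 because of its failed library, and by 5.61 without the 5 libraries. AT5G59732, AT5G49645 and AT3G51238 were at least 33.5-fold, 14.6-fold and 9.49-fold higher. AT1G25055 and AT1G55335 were at 7.75 and 6.44 CPM in WT and 0 in all 3 mutants, with 0, 0 and 87, and 25, 0 and 24 counts in the libraries labelled WT 24 h replicates 1 to 3. AT5G09670 was at 6.07 CPM against 0.673 (1.01 without the failed library), 0 and 0. Without WT 24 h replicate 2, AT5G59732, AT5G49645, AT3G51238 and AT5G09670 were not called (edgeR adjusted p = 0.0613, 0.145, 0.128 and 0.0692), and without replicate 3, AT5G59732, AT5G49645, AT3G51238 and AT1G25055 (0.0646, 0.156, 0.139 and 1). AT3G51238 was also lost without atg2 24 h replicate 1 or the library labelled WT 24 h replicate 1 (1 and 0.0582), AT5G49645 without those (0.0935 and 0.0687), atg2 24 h replicate 2, atg5 24 h replicates 2 or 3 or atg9 24 h replicates 1 or 3 (0.0503 to 0.0572), and AT1G55335 in the DESeq2 Wald test (0.472). The count was 3308, 1444 higher and 1864 lower. It was 1487 and 1628 without WT 24 h replicates 2 and 3, 4421 without the 5 libraries, of which 2898 were shared, 1834 in a fit to its own groups and 2113 with thinned libraries.

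Single mutants at 24 h differed from WT in 1194 genes for atg2 (502 higher, 692 lower), 4503 for atg5 (2404 and 2099) and 2600 for atg9 (1163 and 1437). The largest rises in atg2, LCR11, a defensin-like gene, AT4G06477 and the plastid 16S rRNA gene ATCG00920, were carried by the failed library: 12.16 ± 1.80, 10.92 ± 1.86 and 10.29 ± 2.11, but 5.35, 5.67 and 6.96 without the 5 libraries. ATCG00920 was not called in a fit to its own groups (edgeR adjusted p = 0.196). In atg5, ATMG00500 was at least 45.6-fold higher and ATMG00285 at least 396-fold lower, and both kept their call in every setting. All atg5 24 h libraries are wide. In atg9 24 h, ATMG00500 had 74 and 28 counts in the wide and 0 in the narrow library, and ATMG00285 0, 0 and 101. Class did not part them in every group: the wide dark atg9 library had 0 and 216. ATMG00210 and AT1G18010 were at least 78.2-fold and 26.4-fold higher in atg5, and ATMG00290 and AT1G25055 at least 108-fold and 87.4-fold lower. Without WT 24 h replicate 3 none of these was called (edgeR adjusted p = 0.114, 0.0774, 0.0947 and 1). In atg9, AT5G59732, ATMG00610 and AT1G18010 were at least 34.3-fold, 25.2-fold and 19.1-fold higher, and AT1G25055, AT5G09670 and AT1G55335 at least 82.5-fold, 60.7-fold and 46.5-fold lower, with none called without WT 24 h replicate 3 (0.105, 0.127, 0.166, 1, 0.0832 and 0.0972). Other libraries of atg5, atg9 and WT at 24 h also ended several of these calls, as atg9 24 h replicate 1 did for AT5G59732, ATMG00610, AT5G09670 and AT1G55335 (0.141, 0.0859, 0.133 and 0.132). The bound of AT5G59732 was 12.2-fold without it, and that of AT1G55335 in atg9 29.0-fold without the library labelled WT 24 h replicate 1. With library class as a term AT1G18010 was not called in atg9 (0.0536). In atg2, AT2G19582 was at least 6.58-fold lower (4.19-fold without the library labelled WT 24 h replicate 1), AT3G02832 fell with a ratio of 34.5 (95% counting interval 5.81 to 1403) and AT1G16635 by -4.17 ± 1.04. None was called without atg2 24 h replicate 1 (0.151, 0.139 and 0.0749). The atg2 count was 411 and 505 without atg2 24 h replicates 1 and 3. It was 1931 without the 5 libraries and 2063 with library class as a term. The atg5 count was 2768 without atg5 24 h replicate 2. The atg9 count was 1402 and 1535 without atg9 24 h replicates 1 and 3, and 4050 without the 5 libraries. Without WT 24 h replicates 2 and 3 atg2 had 647 and 655, atg5 2767 and 2766 and atg9 1162 and 1163. Fits to their own groups gave 667, 2275 and 1643, and thinned libraries 671, 2643 and 1332.

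The light response itself was compared between the mutants and WT. At 12 h the seed storage list differed most, with 11 of 14 members lower in the mutants' response, 12 adjusted over the list alone (median difference -4.62 log2, camera adjusted p = 6.38e-37, and adjusted p = 0.000978 with an estimated correlation). CRA1 differed by -4.87 ± 0.66 and kept its call in every setting, whereas OLEO1 (-5.58 ± 0.69) was not called without the 5 libraries. SESA5 went from 0.218 to 18.6 CPM in the libraries labelled WT and from 9.71 to 6.91, 7.27 to 5.16 and 128 to 36.1 in atg2, atg5 and atg9. The WT rise lay in the libraries labelled WT 12 h replicates 1 and 3, and the list median without the 5 libraries was -2.06. The antenna had 0 of 21 called by edgeR, 7 adjusted over the list alone, with a median difference of 1.07 (adjusted p = 1.43e-12, and adjusted p = 0.779 with an estimated correlation), and 15 higher without the 5 libraries (median 2.68). This mean holds the libraries labelled atg5 12 h. For atg2 and atg9 alone the antenna again had 0 called by edgeR (median 1.08, adjusted p = 6.45e-08, and adjusted p = 0.997 with an estimated correlation), and seed storage 11 of 14 lower (median -4.88). Photosystem subunits (median 0.57, adjusted p = 0.00582), jasmonate (0.72, adjusted p = 0.00582), flavonoid (0.74, adjusted p = 0.0293) and senescence genes (-0.67, adjusted p = 0.0293) were also called by camera (each adjusted p = 0.984 with an estimated correlation), and the jasmonate median was -0.24 without the 5 libraries.

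BGLU19, a seed beta-glucosidase, NSP2, a nitrile specifier, and the defensin PDF2.1 had the largest lower differences at 12 h after GASA2 and SESA5, at -7.34 ± 0.87, -7.27 ± 0.89 and -7.07 ± 1.16. GASA2 went from 0 to 0.795 CPM in the libraries labelled WT and from 3.11 to 0.132, 0.699 to 0.533 and 11.5 to 0.896 in the mutants. AT4G22610, AT5G44050, LOX2 and AT1G32970 had higher differences of 3.07 ± 0.65, 3.00 ± 0.54, 2.79 ± 0.68 and 2.70 ± 0.44. AT3G53400 went from 6.50 to 0 CPM in WT and from 7.82 to 7.51, 9.43 to 6.41 and 6.94 to 6.18 in the mutants. Without the 5 libraries, where WT 12 h is 1 library, the calls of these named genes were not kept. The calls of AT3G53400, AT4G22610 and LOX2 were lost without the library labelled WT 12 h replicate 1 (0.0694, 0.0512 and 0.161), and those of AT3G53400, AT4G22610, AT5G44050, LOX2 and GASA2 without that labelled replicate 3 (0.173, 0.0959, 0.0501, 0.194 and 0.282). LOX2 also needed WT 0 h replicates 1, 2 and 3 (0.0511, 0.0692 and 0.0609). The count was 220 (57 higher, 163 lower) and 352 without the 5 libraries, of which 22 were shared and 73.0% higher. It was 99, 496 and 73 without the libraries labelled WT 12 h replicates 1, 2 and 3, 124 and 141 without WT 0 h replicates 1 and 2, 418 without atg5 0 h replicate 1 and 368 without atg5 24 h replicate 1. With no low-count filter it was 530, in a fit to its own groups 670 and with thinned libraries 82. The share called higher was 25.9%, 42.1% with the DESeq2 Wald test and 45.5% with no low-count filter.

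At 24 h, the seed storage list had 5 of 14 members with a lower light response in the mutants, 10 adjusted over the list alone (median difference -2.96 log2, camera adjusted p = 7.11e-13, and adjusted p = 0.176 with an estimated correlation), with OLEO2 at -4.35 ± 0.74. Leaving out the 5 libraries, 3 of 14 were lower (median -0.94, adjusted p = 0.000446, and adjusted p = 0.199 with an estimated correlation). RAB18, a dehydrin, went from 2.35 to 14.3 CPM in WT and from 41.2 to 6.82, 14.7 to 4.79 and 104 to 12.2 in atg2, atg5 and atg9 (-4.75 ± 0.59). The RAB18 means at 24 h were 9.32 in WT and 10.2 in atg2 when the 5 libraries were left out. BGLU19 (-6.18 ± 1.00), AT1G04560 (-5.49 ± 0.68) and AT1G54870 (-5.44 ± 0.86) kept their calls in every setting, while NSP2 (-5.44 ± 1.204) was not called without the library labelled WT 24 h replicate 1 (edgeR adjusted p = 0.265). ATG8e (-1.89 ± 0.31) and the alternative oxidase AOX1A (-1.34 ± 0.25) also had a lower response, and FTM1, a stearoyl-ACP desaturase gene, a higher one (3.49 ± 0.55). AT4G06477 (8.37 ± 1.92), AT2G22650 (4.96 ± 1.201), AAE12 (4.85 ± 1.02) and PYL2, an abscisic acid receptor (3.49 ± 0.94), differed upwards, but none was called without WT 24 h replicate 3 (0.0749, 0.0576, 0.0612 and 0.204). AT4G06477 and AT2G22650 also needed WT 24 h replicate 2 (0.0752 and 0.1), AT2G22650 needed WT 0 h replicate 2 (0.0745), AAE12 needed atg2 24 h replicate 1 (1), and PYL2 was lost without several other libraries. The antenna (median 0.66, adjusted p = 4.32e-07) and photosystem lists (0.49, adjusted p = 0.00759) had 0 members called by edgeR, both with adjusted p = 0.943 at an estimated correlation, and 16 and 21 without the 5 libraries. The count was 355 (112 higher, 243 lower), and 1216 without the 5 libraries, of which 328 were shared. It was 680 without atg5 24 h replicate 1, 146, 163 and 207 without WT 0 h replicates 1, 2 and 3, 553 without the library labelled WT 24 h replicate 1 and 193 and 147 without WT 24 h replicates 2 and 3. A fit to its own groups gave 201, no low-count filter 644 and thinned libraries 235.

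The mutants also differed from one another. Against the mean of atg2 and atg5, atg9 held more seed storage transcripts in the dark, with 12 of 14 higher (median log2 change 2.37, camera adjusted p = 9.14e-32, and adjusted p = 0.00249 with an estimated correlation), at 12 h (12 of 14, median 1.90, adjusted p = 1.06e-20, and adjusted p = 0.0266 with an estimated correlation) and at 24 h (7 of 14, median 1.37, adjusted p = 1.12e-06, and adjusted p = 0.979 with an estimated correlation). Jasmonate genes were lower in dark atg9, with 7 of 10 called (median -1.05, adjusted p = 3.17e-06, and adjusted p = 0.628 with an estimated correlation). Plastid-encoded genes had 35 of 60 lower at 12 h, 38 adjusted over the list alone (median -0.80, adjusted p = 7.55e-34, and adjusted p = 0.264 with an estimated correlation), a comparison that holds the libraries labelled atg5 12 h. Flavonoid genes had 3 of 17 higher in the dark and 6 at 12 h (adjusted p = 0.00185 and 0.0026, and adjusted p = 0.999 and 0.992 with an estimated correlation), and carbon starvation markers 5 of 14 lower at 24 h (adjusted p = 3.42e-05, and adjusted p = 0.979 with an estimated correlation). The counts were 2920 in the dark (1525 higher, 1395 lower), 3517 at 12 h (1789 and 1728) and 973 at 24 h (496 and 477). At 12 h the count was 2125 and 2275 without atg9 12 h replicates 1 and 2. At 24 h it was 613 and 611 without atg2 24 h replicates 1 and 3, 369, 641 and 391 without atg9 24 h replicates 1, 2 and 3, 1929 without the 5 libraries and 467 in a fit to its own groups. A fit to its own groups gave 5372 at 12 h, and thinned libraries gave 1878, 593 and 363. The share called higher was 52.2% in the dark and 51.0% at 24 h, 67.5% and 68.6% with DESeq2 size factors, which moved the median of all genes in the dark to 0.14 (log2), and 41.0% in the dark with the Wald test.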

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

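All tests of explanations in this part were chosen after the results were seen; the tests of difference between light responses and between mutants were planned, except those of atg5 against atg2 and atg9 at 12 h.

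The results below stand out because a direct test found that 2 groups differed. The light response of the mutants differed from that of WT in 220 genes at 12 h and 355 at 24 h, and atg9 differed from the mean of atg2 and atg5 in 2920, 3517 and 973 genes at 0, 12 and 24 h. The 12 h light response of atg5 differed from that of atg2 and atg9 in 1415 genes (732 higher, 683 lower). By list, the differences in light response at 12 h had medians of 1.07 for the antenna, 0.57 for photosystem subunits, -4.62 for seed storage, 0.72 for jasmonate, 0.74 for flavonoids and -0.67 for senescence. At 24 h they were 0.66 for the antenna, 0.49 for photosystem subunits and -2.96 for seed storage. With an estimated correlation only seed storage at 12 h was called by camera (adjusted p = 0.000978). The others at 12 h had adjusted p = 0.779 (antenna) and 0.984, and those at 24 h 0.176 (seed storage) and 0.943. The jasmonate median was -0.24 without the 5 libraries. The named genes at 12 h had edgeR adjusted p = 0.0131 (AT3G53400), 0.00791 (AT4G22610), 0.00122 (AT5G44050), 0.0284 (LOX2), 0.000344 (AT1G32970), 0.00682 (GASA2), 6.57e-06 (SESA5), 3.07e-06 (BGLU19), 3.8e-06 (NSP2) and 0.000375 (PDF2.1). At 24 h they had edgeR adjusted p = 0.0152 (AT4G06477), 0.0223 (AT2G22650), 0.00839 (AAE12), 0.045 (PYL2), 0.000338 (FTM1), 0.000479 (BGLU19), 5.01e-06 (AT1G04560), 0.000368 (AT1G54870), 0.012 (NSP2) and 5.01e-06 (RAB18).

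ATG9 stood near the atg9 level in the libraries labelled WT 12 h replicates 1 and 3 and WT 24 h replicate 1. Shallow depth is argued against, since the ATG9 counts lay under those expected at the lowest level of the other WT libraries (negative binomial with the spread between replicates, highest p = 2.27e-05). A response of WT to light is argued against as the whole cause, since libraries of 1 group differed 4.03-fold or more, against 2.04-fold at most in the other groups, but a smaller one at 24 h is not, with -0.63 (log2, edgeR adjusted p = 0.0183) for ATG9 without the 5 libraries. A wrong label cannot be told apart from a right one. Over genes differing between dark atg9 and WT, each library's difference from another WT library of its group correlated with that change (0.397 or more). CRA1 (134, 130 and 40.3 CPM) was also nearer atg9 of the same time (162 to 167, and 48.4 to 51.7) than other WT libraries (23.8, and 1.19 and 2.41). AT3G32990 was 143, 127 and 142 CPM, as in WT, but it also parts library classes within the mutants, so it cannot decide. No atg9 library had ATG9 at the WT level, so a swap between the 2 groups lacks its partner, and a single wrong label or seedlings of mixed genotype stay open.

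Of 10 clock genes 8 differed in the libraries labelled atg5 12 h: the 12 h response minus that of atg2 and atg9 was 6.34 for CCA1, 6.33 for LHY, 3.48 for PRR9, 3.44 for RVE8, 1.099 for PRR7, -0.86 for TOC1, -2.24 for ELF4 and -1.54 for LUX (log2), with GI (-0.16) and PRR5 (-1.52) not called (edgeR adjusted p = 0.822 and 0.0734). A difference between library classes is argued against, since the 3 libraries, of both classes, lay within 2.38 percentage points of each other. Another harvest time than the label may explain the pattern, since of genes that part 24 h from 12 h in atg2 and atg9 at least 95.2% lay on the 24 h side. An effect of the atg5 genotype cannot be told apart from it, because the same 3 libraries carry both. In atg5 0 h replicate 1, 96.4% of light-responsive genes lay on the light side, against at most 12.6% in the other dark atg5 libraries, which a wrong label may explain.

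The mutants differed from WT in 4431 genes in the dark. Library depth as the whole cause is argued against, since 3397 genes were called with libraries thinned to 1 depth. A difference between batches of libraries cannot be told apart from genotype, because all 9 WT libraries had more AT3G32990 than any mutant library, with the lowest WT value 2.15 times the highest mutant value. Mutant libraries also differ by class: edgeR called 2535 of 19054 genes between the classes, and AT3G32990 was 12.0 to 27.1 CPM in narrow but at most 0.892 in wide mutant libraries. The biological explanation, an effect of losing autophagy on dark seedlings, stays open with it. For seed storage genes, so does a different share of ungerminated seed.

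Splits of the same libraries into groups of the same sizes were also counted. With 10 splits of 6 libraries a share under 0.05 cannot be reached; the real count and the highest of the other splits were 1488 and 0 for WT at 12 h, 2370 and 0 for WT at 24 h, 6144 and 0 and 3588 and 287 for atg2, 0 and 1 and 29 and 1 for atg5, and 4037 and 0 and 1813 and 74 for atg9. Real splits ranked 1 of 10 there except atg5 at 12 h, where 10 of 10 splits called as many. Against WT at 0, 12 and 24 h they were 5276 and 0, 1688 and 1, and 667 and 189 for atg2, 4203 and 0, 1706 and 1, and 2275 and 0 for atg5, and 4589 and 0, 2390 and 0, and 1643 and 0 for atg9. Among 30 splits, 1 (the real one) gave as many genes for the mean of the mutants (4803 against 75, 2919 against 67 and 1834 against 634). The same held for the light responses (670 against 2 and 201 against 1). It also held for atg9 against the mean of the others at 0 and 12 h (2524 against 919 and 5372 against 2141). That share of 0.0333 is the smallest that 30 splits can give, and it was not adjusted for the number of comparisons. Other splits mix groups, which can raise the spread within them, so these ranks alone do not exclude chance. For atg9 against the mean of the others at 24 h, 4 of 30 splits gave as many (467 against 1080), so chance was not excluded. The highest split there put atg2 replicates 1 and 3 with atg9 replicate 2, which points to a structure of the samples other than genotype.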

How the results depend on the processing

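The runs listed earlier as added, and their tests, were chosen only after the results were seen. The others were planned. DESeq2 size factors, length-scaled TPM counts, organelle genes or rRNA genes left out and the DESeq2 Wald test moved no count of genes by over 1.5 times. Among results for named genes that a setting tested, 17 lost their call and 599 kept direction and call with size factors, 57 and 536 with the Wald test, 18 and 598 with length-scaled TPM counts, 63 and 498 in a fit to the compared groups and 121 and 476 with thinned libraries. Where a result changed, the cause was not tested, except that thinning and left-out libraries remove counts or samples by construction. With replicate number as a block, counts were 1524 and 1980 for WT at 12 and 24 h, 321 for atg5 at 12 h, 4448, 2386 and 3247 for the mean of the mutants and 219 and 352 for the light responses. The numbers do not pair the libraries: 13 of 36 libraries were most like a library of their own number, and same-number pairs had a mean correlation of 0.025 across genes (198 pairs) against -0.013 (396 pairs). The block ended the calls of 8 named genes. The second file type held identical estimates and was not run, nor was a log2(TPM) model, as counts were present. All WT libraries are of the wide class, so for mutants against WT the class term rests on class differences within mutant groups. It assumes that WT libraries resemble wide mutant libraries, though AT3G32990 was 58.2 CPM or more in WT and at most 0.892 in those. WT 24 h replicates 2 and 3 had spreads of 118 and 117, nearer the highest narrow (113) than the lowest wide mutant value (168). Class results at 24 h may thus depend on the cut.

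With no low-count filter, edgeR called 1024 genes for atg5 at 12 h and 530 and 644 for the light responses at 12 and 24 h. Fitted to the compared groups, it called 0 for atg5 at 12 h (2314 at an unadjusted p under 0.05; DESeq2 Wald 289), 29 for atg5 at 24 h, 5276 for atg2 against WT at 0 h, 1706 for atg5 against WT at 12 h, 667, 2275 and 1643 for atg2, atg5 and atg9 against WT at 24 h, 1834 for their mean at 24 h, 670 and 201 for the light responses, and 5372 and 467 for atg9 against the others at 12 and 24 h. With library class as a term, atg5 at 12 h had 94 and atg2 against WT at 24 h 2063.

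With thinned libraries the counts were 813 for WT at 12 h, 1404 for atg2 at 12 h, 47 and 1452 for atg5, 984 and 1212 for atg9, 430, 811 and 410 for atg2, atg5 and atg9 against WT at 12 h, 671, 2643 and 1332 at 24 h, 741 and 2113 for their mean at 12 and 24 h, 82 and 235 for the light responses, and 1878, 593 and 363 for atg9 against the others. Depth thus limits how many genes can be called, most at 12 h, where WT held the fewest counts.

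Without the 5 libraries the counts were 2654 and 4268 for atg5 at 12 and 24 h, 1170 and 1322 for atg2 and atg5 against WT at 12 h, 1931 and 4050 for atg2 and atg9 at 24 h, 1192 for the mean at 12 h, 352 and 1216 for the light responses and 1929 for atg9 against the others at 24 h. Of 25 lists, camera called 12, 12 and 11 for the mean of the mutants at 0, 12 and 24 h (5, 1 and 7 with all libraries) and 10 and 12 for the light responses at 12 and 24 h (6 and 3). With an estimated correlation it called 1 and 0 for WT at 12 and 24 h (9 and 9 at the preset), 1, 0 and 0 for the mean of the mutants and 1 and 0 for the light responses.

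Without the 5 libraries the direction reversed for WT at 12 h in SESA5 (-3.82), EM6 (-6.24) and NYE1 (-2.68), for the light response at 12 h in SESA5 (2.78), PDF2.1 (2.15) and NYE1 (2.44), and for the mean of the mutants at 12 h in ATG3 (0.04), GSA1 (0.10), RPI3 (0.067), HLS1 (7.83), CRC (1.296), OLEO1 (0.77), CRA1 (0.67), OLEO2 (1.402), ZAT12 (0.27) and RPN10 (0.57). WT at 12 h was then replicate 2 alone, with 0 counts of SESA5, EM6, PDF2.1 and HLS1 and at most 3 of NYE1, OLEO1 and OLEO2, so the signs of these genes rest on fits to almost no counts and show no measured reversal. Of the lists that camera called in either run, those that reversed were seed storage for WT at 24 h (-0.127; from -0.125 without the library labelled WT 24 h replicate 1 to 1.448 without atg2 24 h replicate 2), jasmonate for the mean at 12 h (-0.65) and photorespiration and jasmonate for the light response at 12 h (0.74 and -0.24). The seed storage median for the mean at 12 h also changed sign, from -1.13 to 1.03, called in neither run (adjusted p = 0.125 and 0.184).

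For atg2 and atg9 alone, without the libraries labelled atg5 12 h, edgeR called 2054 genes for the mean at 12 h and 281 for the light response, and no named gene reversed. Leaving out the 5 libraries as well, it called 1321 and 571. Then, for the light response, SESA5 (2.68), PDF2.1 (1.79) and NYE1 (2.52) reversed. For the mean at 12 h the reversed genes were ATG3 (0.064), GSA1 (0.23), RPI3 (0.38), HLS1 (7.93), LHY (-0.56), CCA1 (-0.97), CRC (2.14, edgeR adjusted p = 0.0109), OLEO1 (1.07), CRA1 (1.601, adjusted p = 0.0143), OLEO2 (1.68), ZAT12 (0.36) and RPN10 (0.64). The same limit holds for the genes with few counts in WT 12 h replicate 2, CCA1 and LHY (2 and 3 counts) among them. The jasmonate list reversed for the mean (-0.82), and photorespiration and jasmonate for the light response (0.83 and -0.18).

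Leaving out each library in turn gave 753 to 1833 genes for WT at 12 h and 1134 to 2251 at 24 h, 2915 to 4541 and 1698 to 3350 for atg2, 4 to 2004 and 1177 to 4120 for atg5, and 2065 to 3571 and 1346 to 2563 for atg9. Against WT at 0, 12 and 24 h, atg2 had 1404 to 2850, 1200 to 2625 and 411 to 1420, atg5 2810 to 4561, 1625 to 3362 and 2766 to 5210, and atg9 3141 to 4861, 965 to 1980 and 1162 to 3079. The mean of the mutants had 2776 to 4831, 1226 to 2825 and 1487 to 3935, the light responses 73 to 496 and 146 to 680, and atg9 against the others 1999 to 3264, 2125 to 3964 and 369 to 1309. Lists called numbered 8 to 10 for WT at 12 h and at 24 h, 5 to 9, 1 to 9 and 4 to 9 for the mean of the mutants, and 4 to 7 and 2 to 10 for the light responses.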

Other observations

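The comparisons of 24 h with 12 h in this part, and the test of the 12 h light response in atg5, were chosen only after the results were seen. Between 12 h and 24 h of light, edgeR called 1137 genes in atg2 (560 higher, 577 lower), 658 in atg9 (345 and 313) and 1299 in atg5 (766 and 533). CCA1 was 1.53 to 1.74 CPM in atg2 and 0.886 to 1.87 in atg9 at 12 h and at least 60.9 CPM in the 24 h libraries other than the failed one, and LHCB3 went from 138 to 741 CPM in atg2 (1028 without the failed library) and from 187 to 1143 in atg9. In the libraries labelled atg5, LHCB3 was 424 CPM in the dark (218 without replicate 1), 890 ± 98.8 at 12 h and 1190 at 24 h.

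HLS1, which keeps the apical hook closed in darkness, was at 6.67 CPM in dark WT and 16.0 at 24 h. ATG8e in WT was at 6.31 ± 1.06 CPM in the dark and 13.5 and 20.3 in the groups labelled 12 h and 24 h, while the dark mutants were already at 37.6, 26.6 and 28.5 in atg2, atg5 and atg9. MLS in WT was at 524 ± 28.5 CPM in the dark and 363 and 164 in the light. Leaving out the doubtful WT libraries, MLS was 229 and 99.9 CPM.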
